A study of Homo sapiens with 16 samples.

How the data were processed

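The series holds 16 Affymetrix expression arrays of human NK cells in 4 groups: primary cells (5 arrays), NKAES-derived cells (5), low dose IL2 culture (3) and high dose IL2 culture (3), the cultures after 7 days. Groups and replicate numbers came from the sample titles. Per the labels, the replicates were grown and harvested independently. RNA input, per the labels' protocols, was 2 µg on 10 arrays (all IL2 arrays, 2 primary, 2 NKAES), 1 µg on 4 (2 primary, 2 NKAES) and 8 µg on 2 (1 primary, 1 NKAES), and entered the alternatives as a block and in subsets but not the group means fitted over all arrays. Scan dates, the array software version and a genome build are not given in the sources used here, so no coordinates are printed and a batch difference between the IL2 arrays and the others cannot be ruled out.

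The deposited values are linear signal intensities, 1 per probe set and array, computed with MAS5 per the submitters' processing notes. MAS5 subtracts the background, combines the probe pairs of a probe set and scales each array to a common trimmed mean. Because the scaling is global, a shift of all genes in one group cannot be seen, and weak signals are noisy, which an offset dampens. The table held 54613 probe sets with values from 0.2 to 79529.3. The mean between the percentiles 2 and 98 ran from 495 to 497 and deviated from that of the median array by at most 0.262%, within the tolerance of 5%, so the values were used without rescaling. Detection calls and control probe sets were not analysed here, which left out the planned check of RNA quality from 3' to 5' signal ratios.

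Gene symbols came from the platform annotation: 41091 probe sets had 1 symbol, 1801 several and 11721 none; only the first kind was named. Of the 41091, 41037 matched a current gene by gene ID and 0 symbols needed an update. The 59 probe sets of XIST, TSIX and Y-linked genes were left out. Values were transformed as log2(value + 16), so changes of dim genes are understated, and a level under the array median was not shown to lie above background. A probe set was kept when it exceeded its array's median on at least 3 arrays (26017 kept), and each gene was represented by its probe set with the highest mean (13149 genes). Where other probe sets of a named gene disagreed with it in direction past the threshold, the text says so.

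Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit over all 16 arrays, which share an estimate of the spread per gene; eBayes with a mean-variance trend), and 6 contrasts were tested, each two-sided with Benjamini-Hochberg adjustment over the 13149 genes and a threshold of 0.05. The design, the comparisons, 26 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists covered cell division, NK cell receptors and effector molecules, cytokines and signalling, transcription factors, interferon and immediate early genes, metabolism and protein folding, apoptosis, and markers of T, B, myeloid and red cells, platelets and the K562 feeder line. Each was tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. List members past the gene test were counted with adjustment over all genes and adjusted over the list alone. Of the 72 camera calls at the preset correlation in the 6 comparisons, 8 held with an estimated one: mitosis and DNA replication against primary cells in all 3 cultures, oxidative phosphorylation in NKAES against primary cells, and T cell markers in high against low dose.

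Genes were named by rule. For NKAES against primary cells these were the 8 largest rises and the 8 largest falls past the threshold whose groups did not overlap; for each other comparison 5 and 5. Up to 4 members of each list with the largest absolute change were added per comparison. XIST, Y-linked, KIR and HLA genes, immunoglobulin and T cell receptor segments and genes absent from some people's genomes were not named on their own. PRSS2 fell under the rule with IL2 but is given no value, because its probe set matches related trypsinogen genes. Genes named in 1 comparison are quoted in others for contrast, and any chosen after their values were seen are marked as such.

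Comparisons that share arrays share their chance deviations. Their overlaps were therefore set beside 100 simulations of unchanged groups, the counts of independent lists, and 10 splits of the shared arrays 2 against 3. The simulations redrew all arrays, with genes independent of each other and the spread of each gene pooled over the groups. The share of signal in the 100 brightest probe sets was compared with exact permutation tests, adjusted over the 6 comparisons. The pipeline was tested on simulated data in which 200 of the 13149 genes were changed: in NKAES against primary cells 48% of changes of 1 and 82% of changes of 2 on the log2 scale were recovered, with 4 false calls, and in NKAES against low dose IL2 32% and 78%, with 9 false calls. Alternatives covered the offset, the filter, the scaling, the variance model, array weights, the arrays in the fit, the replicate number and RNA input as blocks, subsets by RNA input, the choice of probe set and leaving out each array. In these alternatives the gene lists were tested at the preset correlation. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.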

Results

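Messenger RNA of human natural killer (NK) cells was measured on 16 oligonucleotide microarrays in 4 groups. Primary NK cells (5 arrays) were set against NK cells kept for 7 days in 3 kinds of culture: with low dose interleukin 2 (IL2, 3 arrays), with high dose IL2 (3 arrays), or in the NKAES system (5 arrays). NKAES cells are NK cells expanded on K562, an erythroleukaemia line without HLA class I on its surface, modified to carry membrane-bound interleukin 15 and the ligand of the costimulatory receptor 4-1BB. The replicates were separate cell preparations, each on its own array. The 6 comparisons between groups asked how culture altered primary NK cells, how the feeder system differed from IL2 alone, and whether the dose of IL2 mattered. Every array had been scaled by the submitters to a trimmed mean between 495 and 497, and the median probe set read between 81.4 and 109.9. The number of arrays limits the precision. Correlations (Pearson) between arrays of a group, taken across probe sets, which are not independent replicates, were 0.919 to 0.950 in primary cells and 0.902 to 0.951 in NKAES culture. They were 0.947 to 0.954 at low dose and 0.955 to 0.962 at high dose. Differences between groups are given on the log2 scale ± the standard error of the limma fit unless SD is stated. Each adjusted p of a gene is limma's, and each adjusted p of a gene list is that of camera, limma's test of a list against all other genes.

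Of 13149 genes tested, 6164 differed between NKAES-derived and primary cells, 3506 of them higher and 2658 lower. The low dose culture differed from primary cells in 4725 genes (2930 higher, 1795 lower) and the high dose culture in 4943 (3109 higher, 1834 lower). Differences between the cultures were fewer. NKAES differed from low dose IL2 in 697 genes (309 higher in NKAES, 388 lower) and from high dose IL2 in 915 (344 higher, 571 lower). Between the doses limma called 0 genes, and 386 had an unadjusted p under 0.05 where chance gives 657. Changes of at least 2-fold made up 3402, 2707, 2877, 436, 548 and 0 of these counts. The groups did not overlap in 3825 genes for NKAES against primary cells (29.1%, chance 0.794%). For low and high dose IL2 against primary cells they did not overlap in 4752 and 5291 genes (36.1% and 40.2%, chance 3.57%). NKAES was separate from low and high dose in 1794 and 2374 genes (13.6% and 18.1%, chance 3.57%), and the doses from each other in 1754 (13.3%, chance 10%). The median gene differed from primary cells by 0.06 in NKAES, 0.08 at low dose and 0.10 at high dose in the deposited scaling, and by 0.19, 0.25 and 0.27 once every array was centred on its median. Centring raised the share of higher genes from 56.9% to 65.3% for NKAES (3952 higher, 2099 lower). For low dose it rose from 62.0% to 73.3% (3491 and 1269), and for high dose from 62.9% to 73.9% (3778 and 1336).

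**Figure D1:**
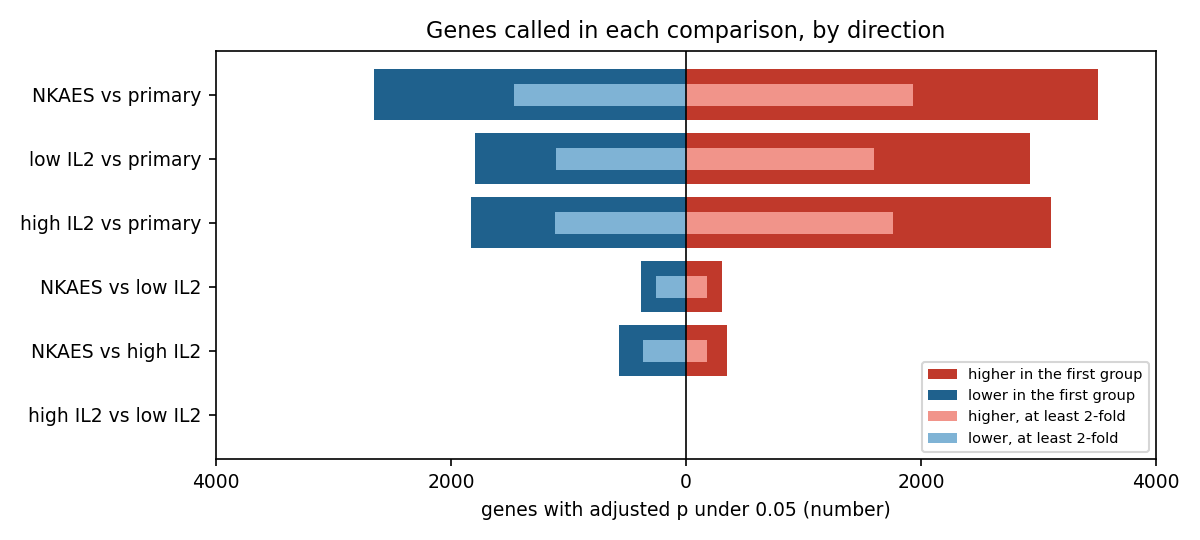
Number of genes past an adjusted p of 0.05 (limma) in each of the 6 comparisons, with higher genes to the right and lower genes to the left of the vertical line and inner bars for changes of at least 2-fold. Comparisons with primary cells gave 4725 to 6164 genes, those of NKAES with IL2 culture 697 and 915, and the IL2 doses 0.

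Against primary cells, NKAES-derived cells carried far more RNA of cell division genes and far less of myeloid genes (5 arrays in each group). BIRC5, or survivin, a chromosomal passenger protein, rose by 6.80 ± 0.30 (adjusted p = 1.13e-11), from 5.23 ± 0.76 to 12.03 ± 0.41 (SD). CDK1, the kinase that drives entry into mitosis, rose by 6.20 ± 0.24, its partner cyclin CCNB2 by 6.47 ± 0.25, and CDC20, which activates the anaphase-promoting complex, by 6.17 ± 0.34. RRM2, a subunit of ribonucleotide reductase, rose by 6.16 ± 0.28, the replication licensing factor CDT1 by 6.06 ± 0.30, DEPDC1 by 6.02 ± 0.19 and the mitotic kinase PBK by 5.89 ± 0.32. S100A8, which with S100A9 forms the calcium-binding protein calprotectin of monocytes and neutrophils, fell by 8.52 ± 0.50 (adjusted p = 5.05e-10). Its level went from 14.39 ± 1.30 to 5.87 ± 0.84 (SD). The lower level of both BIRC5 and S100A8 lay under the array medians, so the size of their changes depended on the offset: with offsets of 1 and 64 it was 7.73 and 5.59 for BIRC5 and -9.01 and -7.61 for S100A8. The next largest falls were in the macrophage gene MS4A7 (-7.77 ± 0.47), S100A9 (-7.35 ± 0.59), S100A12 (-7.33 ± 0.52) and MPEG1, a pore-forming protein of macrophages (-7.18 ± 0.66). The myeloid receptor CLEC5A (-6.92 ± 0.66), GAPT (-6.68 ± 0.64) and thrombospondin THBS1 (-6.48 ± 0.38) followed. The lower group mean of CCNB2, CDC20, CDT1, DEPDC1, PBK, MS4A7, S100A9, S100A12, MPEG1, CLEC5A and GAPT also lay under the array medians. The size and order of their changes thus depend on the offset too. For each of these 16 genes every NKAES array lay on the same side of every primary array, as the rule for naming them required. All 30 measured members of the mitosis list rose (30 adjusted over the list alone), with a median of 5.15 (adjusted p = 1.06e-31, and adjusted p = 0.00961 with an estimated correlation). Of 30 genes for DNA replication and S phase 29 rose (29 adjusted over the list alone), with a median of 3.25 (adjusted p = 4.24e-24, and adjusted p = 0.0193 with an estimated correlation). All 14 monocyte and myeloid markers fell (14 adjusted over the list alone), with a median of -5.49 (adjusted p = 1.19e-09, and adjusted p = 0.239 with an estimated correlation).

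Genes of energy and biosynthetic metabolism were mostly higher in NKAES-derived than in primary cells. Among 20 genes of oxidative phosphorylation and the citrate cycle 18 rose (18 adjusted over the list alone), with a median of 0.95 (adjusted p = 2.97e-08, and adjusted p = 0.0193 with an estimated correlation). The cytochrome c oxidase subunit COX5A rose by 1.81 ± 0.13 and the complex III subunit CYC1 by 1.72 ± 0.14. In glycolysis 15 of 17 genes rose (15 adjusted over the list alone), with a median of 1.28 (adjusted p = 8.27e-05, and adjusted p = 0.407 with an estimated correlation). Glucose-6-phosphate isomerase GPI rose by 2.32 ± 0.24 and triosephosphate isomerase TPI1 by 1.96 ± 0.16. Ribosome biogenesis genes rose in 17 of 18 cases (17 adjusted over the list alone), with a median of 0.83 (adjusted p = 3.20e-05, and adjusted p = 0.407 with an estimated correlation), among them NHP2 (2.11 ± 0.20) and WDR12 (1.85 ± 0.19). Of 17 genes for cholesterol and fatty acid synthesis 11 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 1.00 (adjusted p = 0.00284, and adjusted p = 0.449 with an estimated correlation). The desaturase SCD rose by 3.59 ± 0.52 and the elongase ELOVL6 by 2.70 ± 0.33. Amino acid transport and one-carbon genes rose in 9 and fell in 3 of 16 cases (9 and 3 adjusted over the list alone), with a median of 1.49 (adjusted p = 0.0126, and adjusted p = 0.607 with an estimated correlation). With genes above the 75th percentile on at least 3 arrays their adjusted p was 0.0639 (0.0011 to 0.0639 over the alternatives). PSAT1, an enzyme of serine synthesis, rose by 5.05 ± 0.32 and the folate enzyme MTHFD1 by 3.30 ± 0.13. The cystine transporter SLC7A11 fell by 4.08 ± 0.60.

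The receptors and effector molecules of NK cells moved in both directions between primary and NKAES-derived cells. Among the granzymes, serine proteases of cytotoxic granules, GZMK rose by 3.06 ± 0.36 and GZMA by 1.44 ± 0.23, whereas GZMM fell by 3.06 ± 0.40 and GZMH fell by 2.69 ± 0.39. The granule and death ligand list had 6 of 19 genes higher and 4 lower (6 and 4 adjusted over the list alone), with a median of 0.07 (adjusted p = 0.949). Perforin PRF1 and granzyme GZMB, chosen after their values were seen, averaged 14.64 ± 0.33 and 15.00 ± 0.37 in primary cells (SD). They differed in NKAES by 0.10 ± 0.18 (adjusted p = 0.670) and 0.38 ± 0.17 (adjusted p = 0.0735) and did not pass the test. NCR3, which encodes the activating receptor NKp30, rose by 2.59 ± 0.38. KLRF1, which encodes NKp80, fell by 3.11 ± 0.32, CD160 fell by 2.32 ± 0.49 and SLAMF7 fell by 1.35 ± 0.24. Activating receptors and adaptors rose in 2 and fell in 7 of 16 cases (2 and 7 adjusted over the list alone), with a median of -0.72 (adjusted p = 0.0903, with 0.0223 to 0.241 over the alternatives). The inhibitory receptor CD300A fell by 2.66 ± 0.42 and LILRB1, a receptor of HLA class I, fell by 3.69 ± 0.70. Inhibitory receptors outside the KIR family rose in 2 and fell in 7 of 13 cases (2 and 7 adjusted over the list alone), with a median of -0.84 (adjusted p = 0.0312, and adjusted p = 0.407 with an estimated correlation). Without NKAES replicate 4 the adjusted p of that list was 0.0564 (0.0104 to 0.0728 over its alternatives). Monocytes also carry LILRB1, and on the same arrays the myeloid markers moved by a median of -5.49. KIR genes, also receptors of HLA class I, rose in 4 and fell in 0 of 13 cases (1 and 0 adjusted over the list alone). Their median was 0.72 (adjusted p = 0.101, and adjusted p = 0.793 with an estimated correlation). Their probe sets share sequence, so none is given on its own. The KIR list passed without primary replicate 3 (adjusted p = 0.0373), NKAES replicate 1 (0.0393) or high IL2 replicate 2 (0.0485, with 0.00174 to 0.259 over its alternatives). S1PR5, a sphingosine phosphate receptor needed for NK cell egress from bone marrow and lymph nodes, fell by 3.92 ± 0.41, and CXCR4 fell by 2.40 ± 0.22, while the integrin chain ITGB7 rose by 2.55 ± 0.23. Chemokine and homing receptors rose in 4 and fell in 5 of 20 cases (4 and 5 adjusted over the list alone). Their median was -0.19 (adjusted p = 0.317, and adjusted p = 0.607 with an estimated correlation). Over the alternatives that median ran from -0.86 to 0.16 (adjusted p from 0.00927 to 0.870), and the list passed in the 6 arrays from 1 and 8 µg and in the 4 from 1 µg.

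Cytokine and signalling genes also moved in both directions in NKAES culture, whereas immediate early and interferon response genes were mostly lower. The IL2 receptor chain IL2RA rose by 3.25 ± 0.41 and the feedback inhibitors SOCS2 and CISH by 2.65 ± 0.41 and 2.51 ± 0.44, while the IL7 receptor IL7R fell by 5.68 ± 0.55. Common gamma chain signalling genes rose in 8 and fell in 4 of 22 cases (10 and 4 adjusted over the list alone), with a median of 0.18 (adjusted p = 0.690). The chemokine CCL1 rose by 4.86 ± 0.96, the neutrophil attractant CXCL8 fell by 6.19 ± 1.11 and the inflammatory cytokine IL1B fell by 5.56 ± 0.72. Cytokines and chemokines rose in 7 and fell in 5 of 19 cases (8 and 5 adjusted over the list alone), with a median of 0.04 (adjusted p = 0.949). CD70, a TNF family ligand, rose by 4.20 ± 0.32. The TNF receptor family and NF-kB targets rose in 3 and fell in 9 of 19 cases (3 and 9 adjusted over the list alone). Their median was -0.69 (adjusted p = 0.120, and adjusted p = 0.793 with an estimated correlation). That list passed without primary replicate 3 (-0.92, adjusted p = 0.0305) or NKAES replicate 4 (-0.86, adjusted p = 0.0471, with 5.39e-04 to 0.913 over its alternatives). The transcription factor ZEB2 fell by 3.06 ± 0.28. NK transcription factors rose in 4 and fell in 4 of 21 cases (3 and 4 adjusted over the list alone). Their median was 0.08 but their mean was -0.15, and camera pointed down (adjusted p = 0.777). Of 20 immediate early genes, which respond within minutes to stimulation, 11 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of -0.99 (adjusted p = 8.66e-04, and adjusted p = 0.431 with an estimated correlation). The phosphatase DUSP1 fell by 3.81 ± 0.37 and the nuclear receptor NR4A3 fell by 2.47 ± 0.39. Interferon response genes fell in 12 and rose in 1 of 22 cases (12 and 1 adjusted over the list alone), with a median of -1.51 (adjusted p = 0.00359, and adjusted p = 0.693 with an estimated correlation), and IFIT2 fell by 3.40 ± 0.68. Over the same arrays the myeloid markers moved by a median of -5.49.

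Markers of cells other than NK cells also differed between NKAES-derived and primary cells. MS4A1, the B cell surface protein CD20, fell by 4.33 ± 0.59, and B cell markers fell in 7 and rose in 0 of 10 cases (7 and 0 adjusted over the list alone), with a median of -1.74 (adjusted p = 0.00478, and adjusted p = 0.527 with an estimated correlation). The platelet chemokines PPBP and PF4 changed by -5.81 ± 0.76 and -3.98 ± 0.42. Of 9 erythrocyte and platelet markers 3 passed the test (3 adjusted over the list alone). Their median was -0.41 (adjusted p = 0.0704, and adjusted p = 0.687 with an estimated correlation). Without NKAES replicate 3 or 4 that median was -0.68 or -1.31 (adjusted p = 0.0452 and 0.00711, with 8.35e-04 to 0.698 over the alternatives). The remaining marker past the test, HBB, is left without a direction because its change turned from -5.80 to 0.73 when probe sets shared between related sequences were left out. Without HBB 2 of 8 markers fell, with a median of -0.34. T cell markers rose in 2 and fell in 2 of 11 cases (2 and 2 adjusted over the list alone). Their median was -0.26 but their mean was 0.07, and camera pointed down (adjusted p = 0.669). Genes of MHC class II antigen presentation fell in 1 of 10 cases (1 adjusted over the list alone), with a median of -0.10 (adjusted p = 0.669). On the same arrays the myeloid markers moved by a median of -5.49, so myeloid RNA may have set part of the primary class II level. Markers of the K562 feeder line rose in 4 and fell in 0 of 9 cases (4 and 0 adjusted over the list alone), with a median of 1.32 (adjusted p = 0.329). Their mean level was 7.87 ± 2.06 in NKAES against 6.50 ± 0.33 in primary cells (SD, n = 5 each).

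**Figure D2:**
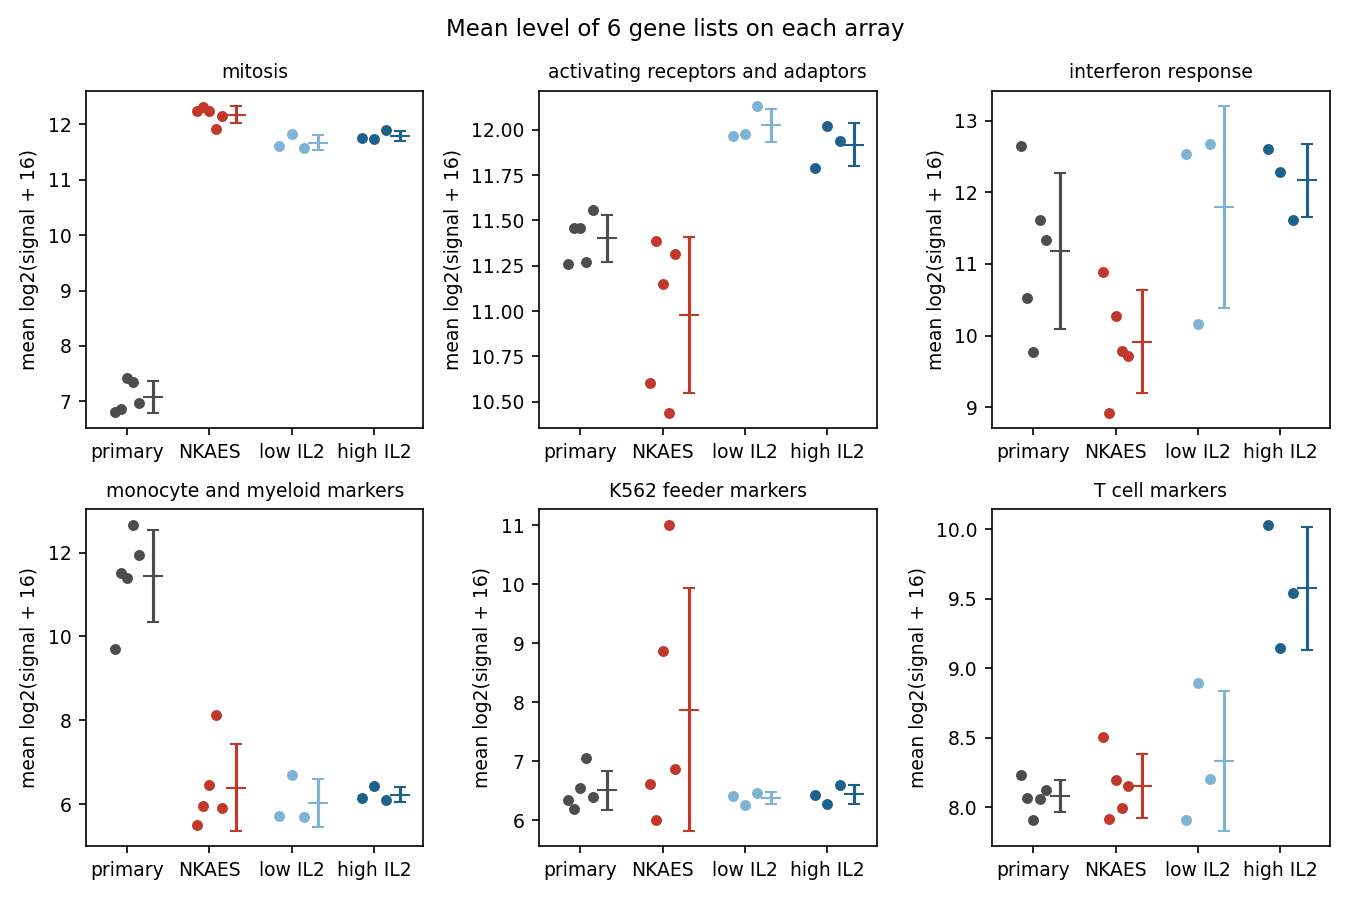
Mean log2 level of 6 gene lists on each array (points), with the mean and SD of each group (bars, n = 5, 5, 3 and 3). Mitosis genes stood at 7.08 in primary cells and at 11.67 to 12.17 in the cultures, myeloid markers at 11.44 and at 6.04 to 6.40, and K562 feeder markers spread most in NKAES (7.87 ± 2.06).

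RNA input differed between arrays: in both the primary and the NKAES group 2 arrays were made from 2 µg, 2 from 1 µg and 1 from 8 µg. Within the 2 µg arrays NKAES and primary cells differed in 4458 genes, within the 4 arrays from 1 µg in 1323, and with input as a block in 6458. The 8 µg arrays, 1 against 1, allowed no test. The mitosis list moved by 5.36 within the 2 µg arrays and 4.72 within the 1 µg arrays, and the myeloid markers by -5.45 and -4.45. Immediate early genes moved by -1.63 and -0.27, and interferon genes by -1.77 and -0.99. The TNF receptor and NF-kB list moved by -1.30 at 2 µg (adjusted p = 5.39e-04) and by 0.15 at 1 µg (0.913, which are also the extremes over its alternatives). K562 feeder markers moved by 0.15 at 2 µg (adjusted p = 0.870) and by 2.80 at 1 µg (9.70e-04, with 9.70e-04 to 0.879 over the alternatives). Among the genes named above, CCL1 missed the threshold within the 2 µg arrays, where it differed by 3.41. CXCL8, IL1B, LILRB1, GZMA, CD300A, NCR3, CD160, IFIT2, CISH, SLAMF7 and SLC7A11 missed it within the 4 arrays from 1 µg, where only 2 arrays stood against 2. All kept their direction there: they differed, in that order, by -2.43, -3.65, -3.17, 1.20, -2.23, 1.85, -2.18, -2.58, 2.35, -1.87 and -4.73. Of the 26 lists, 12 passed camera at the preset correlation over all arrays. With an estimated correlation 3 passed (mitosis, DNA replication and oxidative phosphorylation), and the other 9 had adjusted p from 0.239 to 0.693.

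After culture with low dose IL2 (3 arrays against 5) cell division genes were also higher, and myeloid genes lower, than in primary cells. BIRC5 rose by 6.27 ± 0.34 (adjusted p = 4.10e-10), PSAT1 by 5.80 ± 0.37, CDT1 by 5.73 ± 0.35, CDK1 by 5.73 ± 0.27 and PBK by 5.71 ± 0.37. CXCL8 fell by 8.64 ± 1.28 (adjusted p = 5.31e-05), and S100A8 changed by -8.22 ± 0.58, MS4A7 by -7.96 ± 0.55, S100A9 by -7.88 ± 0.68 and IL1B by -7.67 ± 0.83. All of these genes except PSAT1 and CDK1 had a lower group mean under the array medians. The size and order of their changes thus depend on the offset. Among targets of IL2 signalling, CISH rose by 5.08 ± 0.51, SOCS2 by 4.15 ± 0.47 and the survival gene BCL2 by 3.36 ± 0.34, while IL7R fell by 5.93 ± 0.64. The lymphotoxin genes LTA and LTB rose by 5.66 ± 0.91 and 5.25 ± 0.67, NCR3 by 4.26 ± 0.44 and the death ligand TNFSF10 (TRAIL) by 2.25 ± 0.42. The chemokine receptor CCR6 rose by 3.25 ± 0.56, and CCR7, which guides cells into lymph nodes, fell by 3.95 ± 0.59. All 30 mitosis genes rose (30 adjusted over the list alone), with a median of 4.64 (adjusted p = 2.25e-36, and adjusted p = 0.00533 with an estimated correlation), as did 29 of 30 DNA replication genes (29 adjusted over the list alone), with a median of 3.12 (adjusted p = 5.15e-27, and adjusted p = 0.0190 with an estimated correlation). All 14 myeloid markers fell (14 adjusted over the list alone), with a median of -5.95 (adjusted p = 2.16e-12, and adjusted p = 0.131 with an estimated correlation). The 13 KIR genes all rose (13 adjusted over the list alone), with a median of 2.14 (adjusted p = 3.09e-05, and adjusted p = 0.434 with an estimated correlation). Of 10 genes for MHC class II presentation 8 fell (9 adjusted over the list alone), with a median of -1.79 (adjusted p = 6.87e-05, and adjusted p = 0.434 with an estimated correlation). Among primary arrays the mean levels of these genes and of the myeloid markers were both lowest on replicate 1 (11.54 and 9.71). Both were highest on replicate 4 (13.92 and 12.67). A loss of myeloid RNA was therefore not told apart from a fall of class II genes within NK cells. Of the 26 lists, 12 passed camera at the preset correlation and 2, mitosis and DNA replication, with an estimated one, where the other 10 had adjusted p from 0.131 to 0.493. The arrays at 2 µg (2 primary, 3 low dose) gave medians of 4.82 for mitosis and -4.95 for myeloid markers.

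After culture with high dose IL2 (3 arrays against 5 of primary cells) cell division genes were likewise higher and myeloid genes lower. BIRC5 rose by 6.56 ± 0.34 (adjusted p = 2.21e-10), PBK by 6.20 ± 0.37, the mitotic kinesin KIFC1 by 5.91 ± 0.26 and CDK1 by 5.89 ± 0.27. CXCL8 fell by 9.27 ± 1.28 (adjusted p = 2.43e-05), and S100A8 changed by -7.92 ± 0.58, the chemokine CXCL2 by -7.37 ± 1.04, CLEC5A by -7.24 ± 0.76 and RIN2 by -7.20 ± 0.56. All of these genes except CDK1 had a lower group mean under the array medians. The size and order of their changes thus depend on the offset. CISH rose by 5.24 ± 0.51, CCR6 by 3.34 ± 0.56 and LAG3, an inhibitory receptor of activated lymphocytes, by 4.10 ± 0.64. LTB rose by 5.38 ± 0.67, but its other probe set was called in the opposite direction. T cell markers rose in 7 and fell in 1 of 11 cases (7 and 1 adjusted over the list alone). Their median was 1.71 (adjusted p = 0.0774, and adjusted p = 0.532 with an estimated correlation). Without high IL2 replicate 2 their median was 2.07 and their adjusted p 0.0322 (0.0238 to 0.362 over the alternatives). The T cell signalling gene THEMIS rose by 4.27 ± 0.65 and the CD3 chain CD3D by 3.29 ± 0.41. All 30 mitosis genes rose (30 adjusted over the list alone), with a median of 4.80 (adjusted p = 3.99e-35, and adjusted p = 0.00621 with an estimated correlation), as did 29 of 30 DNA replication genes (29 adjusted over the list alone), with a median of 3.19 (adjusted p = 1.46e-25, and adjusted p = 0.0233 with an estimated correlation). All 14 myeloid markers fell (14 adjusted over the list alone), with a median of -5.75 (adjusted p = 9.41e-12, and adjusted p = 0.15 with an estimated correlation). KIR genes rose in 6 of 13 cases (7 adjusted over the list alone), with a median of 1.02 (adjusted p = 0.0221, and adjusted p = 0.649 with an estimated correlation). Without high IL2 replicate 2 that list had a median of 0.49 and an adjusted p of 0.227 (4.80e-04 to 0.227 over its alternatives). Of the 26 lists, 13 passed camera at the preset correlation and 2, mitosis and DNA replication, with an estimated one, where the other 11 had adjusted p from 0.15 to 0.649. The 2 µg arrays (2 primary, 3 high dose) gave medians of 4.90 for mitosis and -4.96 for myeloid markers.

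Many genes called in 1 culture against primary cells were called in another. NKAES and high dose IL2 were both higher than primary cells in 2540 genes, against 829 for independent lists of those sizes, and both lower in 1417 against 371, with 18 genes in opposite directions. NKAES and low dose IL2 shared 2487 higher genes (781 if independent) and 1430 lower (363), with 15 opposite. The IL2 doses shared 2597 (693) and 1415 (250), with 0 opposite by limma. Across genes, which are not independent replicates, the log2 changes correlated at 0.847 for NKAES and high dose, 0.857 for NKAES and low dose and 0.948 for the doses. Simulations that redrew all arrays without group differences, the primary arrays shared by both comparisons, gave 0.433, 0.432 and 0.374. Genes varied independently in them, so deviations that genes share on an array are missing from this baseline. With the primary arrays split 2 against 3 the observed correlations ran from 0.742 to 0.792, from 0.745 to 0.80 and from 0.834 to 0.886. The covariance of the changes was 1.21, 1.21 and 1.31, against 0.0586, 0.0585 and 0.0584 simulated. Split primary arrays gave 1918 to 2003 shared higher genes for NKAES and high dose, 1909 to 1961 for NKAES and low dose, and 1766 to 1979 for the doses. The shared calls of the doses, 4012 in both directions together, came to 2617 in the lowest split.

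Compared with low dose IL2 (5 arrays against 3), NKAES-derived cells carried more VCAM1, MYB and TNFSF4 RNA and less GEM, DLL1 and CDH17 RNA. Whether the IL2 arrays were run in another batch than the primary and NKAES arrays is not given, so each comparison of IL2 culture with those groups could carry a batch difference. The adhesion molecule VCAM1 was higher by 5.57 ± 0.75 (adjusted p = 4.69e-04), the transcription factor MYB by 4.65 ± 0.50 and the costimulatory ligand TNFSF4 (OX40 ligand) by 4.55 ± 0.48. The receptor GPR55 was higher by 4.28 ± 0.45, the regulator of G protein signalling RGS1 by 4.19 ± 0.61 and CCR7 by 3.61 ± 0.59. GEM, a small GTP-binding protein, differed by -5.07 ± 0.48 (adjusted p = 4.15e-05), DRAXIN by -4.95 ± 0.53, the Notch ligand DLL1 by -4.73 ± 0.46, the cadherin CDH17 by -4.62 ± 0.48 and the TNF family ligand TNFSF14 by -3.93 ± 0.51. The receptor SLAMF7 (-1.44 ± 0.27) and the early response factor EGR3 (-3.15 ± 0.48) were lower as well. So were LTB (-3.82 ± 0.67), CCR6 (-3.38 ± 0.56), GZMM (-2.77 ± 0.47) and CD160 (-3.09 ± 0.57), all of which missed the threshold within the 2 µg arrays (-3.38, -2.59, -2.25 and -2.63 there). Of the genes with the largest differences, VCAM1, GPR55, DRAXIN, DLL1 and CDH17 had a lower group mean under the array medians. The size and order of their differences thus depend on the offset. Activating receptors and adaptors fell in 5 of 16 cases (8 adjusted over the list alone), with a median of -0.85 (adjusted p = 8.96e-08, and adjusted p = 0.125 with an estimated correlation). Interferon response genes fell in 5 of 22 cases (14 adjusted over the list alone), with a median of -1.79 (adjusted p = 1.76e-09, and adjusted p = 0.363 with an estimated correlation) and of -1.36 within the 2 µg arrays. That median was -2.52 without low IL2 replicate 2, whose signal for these genes was lower than in the other low dose arrays, and -1.40 without low IL2 replicate 3. Of 13 KIR genes 0 were called by limma over all genes and 13 fell when adjusted over the list alone, with a median of -1.30 (adjusted p = 7.87e-08, and adjusted p = 0.296 with an estimated correlation). MHC class II genes rose in 5 of 10 cases (8 adjusted over the list alone), with a median of 1.71 (adjusted p = 2.47e-09, and adjusted p = 0.199 with an estimated correlation). Oxidative phosphorylation and citrate cycle genes rose in 5 of 20 cases (13 adjusted over the list alone), with a median of 0.44 (adjusted p = 6.34e-08, and adjusted p = 0.0587 with an estimated correlation). K562 feeder markers had a median of 1.34 with 0 of 9 genes called by limma and 0 adjusted over the list alone (adjusted p = 0.0176, and adjusted p = 0.567 with an estimated correlation). Their median was 0.09 without the NKAES arrays from 1 µg, and their adjusted p was 0.0505 without NKAES replicate 3, 0.189 without NKAES replicate 4 (median 0.73) and 0.0645 without low IL2 replicate 2 (0.00104 to 0.838 over the alternatives). Of the 12 lists past camera 0 passed with an estimated correlation, where their adjusted p ran from 0.0587 to 0.567. The count of 697 genes came to 194 without low IL2 replicate 1, 198 without low IL2 replicate 3, 399 when only the 8 arrays compared were fitted and 387 within the 2 µg arrays. It came to 424 without the NKAES arrays from 1 µg, an alternative chosen after the data were seen, and to 1395 with array weights.

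**Figure D3:**
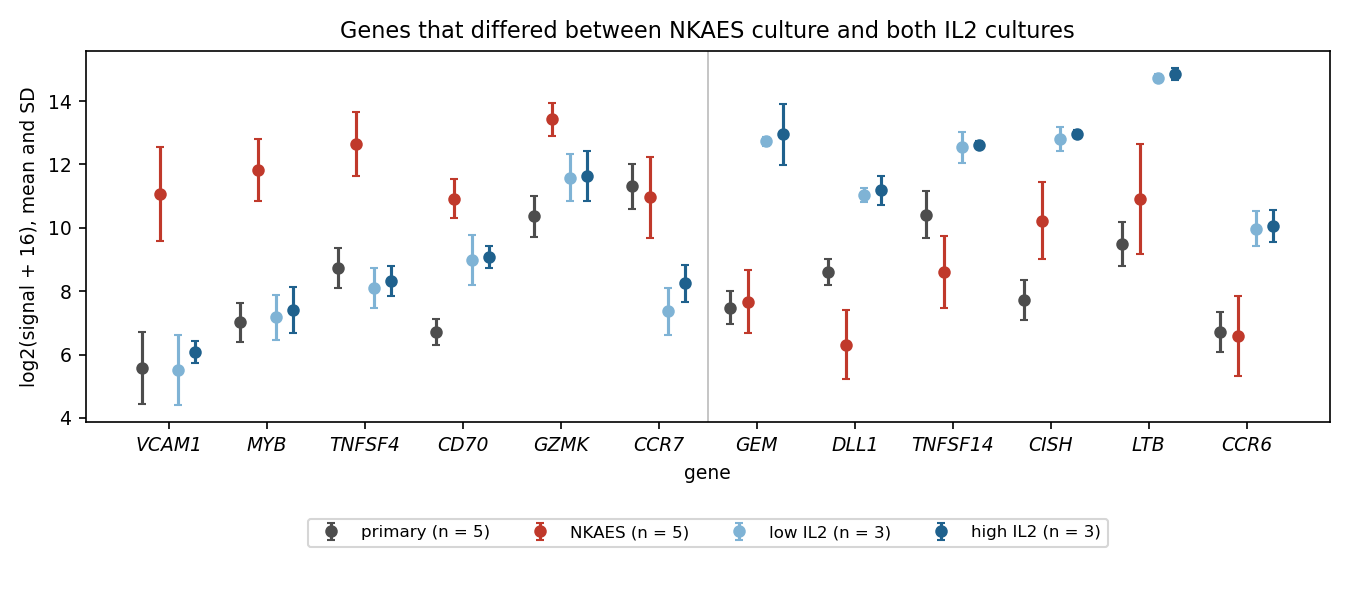
Log2 signal of 12 genes as the mean (points) and SD (bars) per group (n = 5, 5, 3 and 3), 6 higher and 6 lower in NKAES than in IL2 culture. VCAM1 averaged 11.08 in NKAES and 5.52 and 6.09 with low and high dose IL2, and GEM averaged 7.66, 12.74 and 12.95.

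VCAM1, MYB and TNFSF4 RNA was also higher, and GEM, CDH17 and DLL1 RNA lower, in NKAES than in high dose IL2 culture (5 arrays against 3). VCAM1 was higher by 4.99 ± 0.75 (adjusted p = 0.00103), MYB by 4.42 ± 0.50, TNFSF4 by 4.33 ± 0.48, ZC3H12C, of a ribonuclease family, by 4.23 ± 0.53 and the adenylate kinase AK4 by 3.84 ± 0.64. GEM differed by -5.29 ± 0.48 (adjusted p = 2.00e-05), CDH17 by -5.15 ± 0.48, DLL1 by -4.87 ± 0.46 and the interferon-induced gene IFI44L by -5.53 ± 1.07. LTB (-3.95 ± 0.67), CCR6 (-3.46 ± 0.56), CISH (-2.74 ± 0.51), CD300A (-2.61 ± 0.48), GZMH (-2.24 ± 0.44), EGR3 (-2.47 ± 0.48) and SLAMF7 (-1.39 ± 0.27) were lower, and the cytochrome c oxidase subunit COX5B was higher by 0.63 ± 0.12. Within the 2 µg arrays GZMH (-2.29), IFI44L (-4.80) and LTB (-3.52) missed the threshold, as did LTB with all its probe sets averaged (-1.49). VCAM1, ZC3H12C, AK4, CDH17 and DLL1 had a lower group mean under the array medians. The size and order of their differences thus depend on the offset. T cell markers fell in 4 of 11 cases (7 adjusted over the list alone), with a median of -1.56 (adjusted p = 5.09e-05, and adjusted p = 0.0518 with an estimated correlation), and CD3D differed by -3.49 ± 0.41. B cell markers fell in 7 of 10 cases (7 adjusted over the list alone), with a median of -1.84 (adjusted p = 1.08e-06, and adjusted p = 0.267 with an estimated correlation), and MS4A1 differed by -4.31 ± 0.68. Activating receptors and adaptors fell in 7 of 16 cases (9 adjusted over the list alone), with a median of -0.88 (adjusted p = 2.56e-06, and adjusted p = 0.148 with an estimated correlation). Interferon response genes fell in 10 of 22 cases (18 adjusted over the list alone), with a median of -2.04 (adjusted p = 3.36e-11, and adjusted p = 0.297 with an estimated correlation) and of -1.73 within the 2 µg arrays. K562 feeder markers had a median of 1.39 with 0 of 9 genes called by limma and 0 adjusted over the list alone (adjusted p = 0.0146, and adjusted p = 0.449 with an estimated correlation). Their median was 0.15 without the NKAES arrays from 1 µg, and their adjusted p was 0.164 without NKAES replicate 4, where their median was 0.67 (8.36e-04 to 0.799 over the alternatives). Of the 14 lists past camera 0 passed with an estimated correlation, where their adjusted p ran from 0.0518 to 0.449. The count of 915 genes came to 272, 339 and 461 without high IL2 replicates 2, 1 and 3, and to 599 without NKAES replicate 3. It came to 603 with RNA input as a block, 424 within the 2 µg arrays, 574 without the NKAES arrays from 1 µg and 2191 with array weights.

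Against both IL2 cultures 188 genes were higher in NKAES (8.08 for independent lists) and 308 lower (16.8). NKAES was higher than all 3 other groups in 134 genes and lower in 201. The counts of 188 and 308 came to 65 and 104 without low IL2 replicate 1, 73 and 99 without low IL2 replicate 3, and 111 and 223 without NKAES replicate 3. Without high IL2 replicates 1, 2 and 3 they came to 83 and 166, 72 and 139, and 104 and 194. Those of 134 and 201 came to as few as 49 and 65 without low IL2 replicate 1, with 51 and 66 without low IL2 replicate 3 and 86 and 153 without NKAES replicate 3. Without high IL2 replicates 1, 2 and 3 they were 59 and 103, 54 and 95, and 78 and 133. The log2 changes of NKAES against the IL2 cultures correlated at 0.829 across genes, and their covariance was 0.351. Simulations with all arrays redrawn, the NKAES arrays shared and genes independent, gave 0.375 and 0.0585. With the NKAES arrays split 2 against 3 the correlation ran from 0.447 to 0.656, and 40 to 76 genes were shared as higher and 55 to 148 as lower.

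High and low dose IL2 (3 arrays each) were not separated in any gene by limma, and of the 26 lists T cell markers alone passed camera with an estimated correlation. CD3D differed by 2.55 ± 0.46 (limma adjusted p = 0.487, the smallest of any gene), THEMIS by 3.32 ± 0.73 (0.723) and the CD3 chain CD3G by 1.75 ± 0.61 (1.000). The T cell markers averaged 9.57 ± 0.44 at high dose and 8.33 ± 0.50 at low dose (SD, n = 3 each). By limma 0 of 11 were called over all genes and 3 rose when adjusted over the list alone, and their median was 1.02 (adjusted p = 1.08e-09, and adjusted p = 0.00492 with an estimated correlation). Over the alternatives that median ran from 0.52, with genes above the 75th percentile on at least 3 arrays, to 1.34, without high IL2 replicate 3 (adjusted p from 1.50e-12 to 0.0017). KIR genes had a median of -1.02 (adjusted p = 1.33e-10, and adjusted p = 0.415 with an estimated correlation) and MHC class II genes of 0.72 (adjusted p = 4.81e-05, and adjusted p = 0.457 with an estimated correlation). Immediate early genes had a median of -0.36 (adjusted p = 8.13e-05, and adjusted p = 0.457 with an estimated correlation) and B cell markers of 0.84 (adjusted p = 4.92e-05, and adjusted p = 0.457 with an estimated correlation). Adjusted over the list alone, 2 MHC class II genes rose and 0 genes of the other 3 lists were called. The KIR median was -0.52 without high IL2 replicate 1 and -1.55 without high IL2 replicate 2, and that of the immediate early genes -0.59 without low IL2 replicate 1. B cell markers had a median of 0.50 without low IL2 replicate 1 and of 0.48 without high IL2 replicate 1, where their adjusted p was 0.0779 (1.77e-10 to 0.0779 over the alternatives). With only the IL2 arrays fitted, limma also called 0 genes, and 950 had an unadjusted p under 0.05 where chance gives 657. Simulated data used the spread of each gene pooled over all groups. In them 28% of genes changed by 1 and 75% of genes changed by 2 on the log2 scale were recovered in this comparison. These shares therefore do not describe the spread of the IL2 arrays alone. Leaving out high IL2 replicate 1 or replicate 3 gave 1 gene, and array weights 3.

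The share of an array's summed signal held by its 100 brightest probe sets was 10.8 ± 0.888% in primary cells, 10.3 ± 0.639% in NKAES, 9.72 ± 0.650% at low dose and 9.33 ± 0.546% at high dose (SD, n = 5, 5, 3 and 3). Two-sided exact permutation tests gave p-values from 0.0714 to 0.5 over the 6 comparisons, 0.268 to 0.5 after adjustment. The smallest p such a test allows is 0.00794 with 5 arrays against 5, 0.0179 with 5 against 3 and 0.1 with 3 against 3.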

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

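Each test in this part was fixed ahead of the results. In groups of 5 arrays, a gene was picked out when its highest or lowest array lay further from its nearest neighbour than 0.71 of the group's whole range. Chance picks out about 1 in 20 groups, and 16 of 294 group values were picked out here, so the number alone does not stand apart from chance.

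Among primary arrays, the lowest array stood apart for CD300A (gap of 0.736 of the range), LYZ (0.79), NCR2 (0.814), PBK (0.763) and RIN2 (0.732), and the highest for LEF1 (0.717), SCD (0.711), SLAMF7 (0.805) and TNFSF4 (0.82). Among NKAES arrays, the lowest array stood apart for the cell division genes CDC20 (0.826), CDK1 (0.816) and RRM2 (0.889) and for ZC3H12C (0.756), and the highest for IRF4 (0.723), S100A8 (0.807) and SIGLEC9 (0.821). No explanation was tested for these values.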

How the results depend on the processing

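Alternatives chosen after the data were seen were those without the NKAES arrays from 1 µg, with the 4 arrays from 1 µg alone, and the one aimed at the low interferon signal of 1 low dose array; the others were planned. Of 373 called values of named genes, 242 kept their call and direction under every alternative run and 297 with each array left out. Against primary cells 208 of 281 held under every alternative, but between NKAES and IL2 culture only 34 of 92. Of 11646 gene values compared, 548 lost the call and 4 reversed. TNFRSF9 in NKAES against primary cells turned to -0.38 within the 2 µg arrays; HBB turned to 0.73, 0.12 and 1.03 (NKAES, low and high dose against primary cells) without probe sets shared between related sequences. The interferon response list between the doses missed the threshold over all arrays (median 0.32, adjusted p = 0.122) but passed it downward without low IL2 replicate 2 (-0.51, adjusted p = 0.00522) and upward without low IL2 replicate 1 (0.55, 0.00331), low IL2 replicate 3 (0.65, 2.52e-04) or high IL2 replicate 3 (0.52, 0.00607), with 2.52e-04 to 0.860 over its alternatives. The cause of these turns was not tested. The 72 calls over the gene lists came to 8 with an estimated correlation, a stricter test by construction, and to 72 to 78 with each array left out. For NKAES against primary cells the count of 6164 came to 3425 in the 6 arrays from 1 and 8 µg and 1323 in the 4 arrays from 1 µg (fewer arrays), and to 5751 to 6199 with each array left out; low and high dose against primary cells gave 3737 to 5005 and 3810 to 5223. For NKAES against low dose, 697 came to 1395 with array weights, 399 with only the arrays compared, 387 within the 2 µg arrays, 424 without the NKAES arrays from 1 µg, and 194 to 816 with each array left out. For NKAES against high dose, 915 came to 2191 with array weights, 603 with RNA input as a block, 424 within the 2 µg arrays, 574 without the NKAES arrays from 1 µg, and 272 to 1033 with each array left out. For the doses, 0 came to 1 with an offset of 64, 3 with array weights and 0 to 1 with each array left out. Shared calls of low and high dose against primary cells, 4012, came to 2617 in the lowest split of the primary arrays. For changes without fewer arrays the cause was not tested. Same-numbered primary and NKAES arrays deviated together only weakly (lowest correlation 0.0732, highest 0.251), so the numbers were not treated as pairs. Yet 5 of 5 correlated best with their own number, and arrays of equal number also had equal RNA input. Whether equal numbers mark a shared donor is not given in the sources used here, and a part of the shared input in these correlations was not tested. The replicate block gave 6525, 4787, 5044, 751, 1044 and 2 genes in the 6 comparisons, and 6065 for the 10 primary and NKAES arrays alone. The check with GAPDH or ACTB alone for RNA quality was not run, as control probe sets were not analysed here. Signal over background limits dim genes most, and detection calls were not used.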

Other observations

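The tests of lower RNA input and of median centring for the myeloid markers, and the counts without the NKAES arrays from 1 µg, were chosen after the result was seen, and the limits for excluding lower RNA input were revised after that. Genes of cell death moved in both directions in culture. Of 21 apoptosis regulators, 7 rose and 6 fell in NKAES against primary cells (7 and 6 adjusted over the list alone; median 0.07, camera direction down, adjusted p = 0.949). The death receptor FAS rose in all 3 cultures, by 1.39 ± 0.13 in NKAES, 1.13 ± 0.15 at low dose and 1.34 ± 0.15 at high dose (limma; adjusted p = 1.18e-07, 1.32e-05 and 1.83e-06). BAX, which permeabilises mitochondria, rose by 0.78 ± 0.19, 0.98 ± 0.23 and 1.81 ± 0.23, and BID changed by -1.44 ± 0.34 in NKAES (adjusted p = 0.00218). The unfolded protein response list rose in 7 and fell in 5 of 20 cases in NKAES (7 and 5 adjusted over the list alone; median -0.05, mean 0.08; camera adjusted p = 0.977). SDF2L1, a chaperone cofactor of the endoplasmic reticulum, rose by 1.42 ± 0.30, 1.45 ± 0.35 and 1.92 ± 0.35 in the 3 cultures, while the stress factor DDIT3 changed by -1.36 ± 0.25 in NKAES (limma adjusted p = 2.64e-04).

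Myeloid transcripts were lower in all 3 cultures than in primary cells. A hypothesis is that primary samples held RNA of monocytes that the cultures lost. Monocyte genes held out of the list moved the same way, with a smallest median of -3.59 over the 3 cultures. Across the primary arrays 86.1% of the variance of the myeloid list lay on a single component, against a median of 53.6% for random lists. Genes that vary together for any reason would tend to exceed random lists, so this share cannot decide about a common source. With arrays centred on their median, the smallest median fall of the list was -5.36. The array medians lay between 81.4 and 109.9, so centring could not have removed a fall of this size and could not decide about scaling. A lower content of these transcripts within the NK cells after culture was not tested and stays open.

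K562 feeder transcripts were higher in the NKAES arrays made from 1 µg RNA than in the other NKAES arrays, by a median of 3.73. Residual feeder cells may account for this: held-out K562 genes differed by 2.42, and the embryonic globin HBZ averaged 12.5 against 6.10 on the log2 scale, with 5.55 and 5.05 in the matching primary arrays. Between primary arrays of 1 µg and the other primary arrays the same list differed by only 0.50 (upper end of the bootstrap interval 0.686). This argues against lower RNA input as the whole cause. A smaller part for input stays open, as the held-out genes differed there by 0.77 (0.0876 to 1.13). These intervals resampled genes and not arrays, so they leave out the spread between the few arrays. Input as the whole cause is therefore not excluded. Red cells or their precursors among the cultured cells stay open, as 5 adult red cell genes differed by a median of 2.98 (0.635 to 4.77, genes resampled). These include HBB, whose direction against primary cells depended on the choice of probe set.

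T cell transcripts were higher with high than with low dose IL2. T cells in the high dose cultures are a candidate explanation. CD3 genes had a median difference of 1.75 (bootstrap interval 0.597 to 2.55, CD3E 0.60). T cell genes outside CD3, of which CTLA4 and LEF1 also belong to other lists, had 0.47 (bootstrap interval 0.124 to 1.30). The held-out genes among them alone had 0.14 (-0.292 to 1.65). These intervals resampled genes and not arrays, so they leave out the spread between arrays, and they overlap. Several genes outside CD3 were already high at low dose, such as LAT (11.02), BCL11B (11.09) and LEF1 (10.96). Added T cells might hardly raise such genes, so the lower medians cannot count against T cells. Among genes dimmer at low dose, THEMIS (5.87 there) and SIT1 (6.45) differed by 3.32 and 2.78. CD4 (6.01) and CTLA4 (6.32) differed by only 0.57 and 0.39. More T cells therefore cannot be told apart from a rise of CD3 genes in other cells with 3 arrays a group. The lower median rise with rescaled arrays was 1.03 against 1.02 in the deposited scaling, so the rise did not depend on which of these scalings was used. The medians of the IL2 arrays lay between 83 and 91.1, so centring could not have removed the rise and could not decide about scaling. An effect of dose on NK cells themselves was not tested.

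Other splits of the arrays into groups of the same sizes were fitted for each count of genes. Chance was made unlikely, though not excluded, where the real split, counted as 1, gave the most genes of the splits fitted. These were NKAES against primary cells (6164 genes, highest of the other splits 1089, 100 splits), low dose against primary cells (4725, 381, 56 splits), high dose against primary cells (4943, 444, 56 splits), NKAES against low dose (697, 80, 56 splits) and NKAES against high dose (915, 97, 56 splits). The 100 splits were a sample of those possible. The shares were not adjusted over the comparisons, and a batch difference of the IL2 arrays would also set the real split apart. For the IL2 doses the 10 splits are too few for a share under 0.05; the real count was 0 by limma, with 386 genes at an unadjusted p under 0.05, and the highest other was 0.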
